A study of Escherichia coli str. K-12 substr. MG1655 with 20 samples.

How the data were processed

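Ribosome-protected mRNA fragments were measured in 20 libraries of Escherichia coli MG1655, 10 of a lambda cI857 lysogen and 10 of the strain without the prophage. Per the labels, cultures at an OD600 of 0.4 to 0.5 were moved from 32 °C to 42 °C, treated with chloramphenicol (0.1 mg/ml) for 2 min before harvest, and digested with micrococcal nuclease. Monosomes were taken from a sucrose gradient, fragments of 28 to 42 nt were cut from a gel, tailed with poly(A), reverse transcribed with barcoded primers, circularised, amplified and sequenced on a HiSeq 2000.

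The authors deposited 1 table per library with an RPKM value (reads per kilobase of the frame, scaled by the reads of the library) for each of 4154 host and 73 lambda frames. The design had first assumed read counts, so the unit differed from what it assumed. In the deposited tables, value times length fell on whole multiples of a step per library for 100% of the values under 200 reads, within 0.05 reads, and this gave the reads behind each value and the depth. The aligner, the annotation and the genome build are not given in the sources used here. Lambda frames have coordinates that follow those of the host. Of the host names, 3829 were RefSeq symbols and 296 synonyms of the reference annotation, which was used for names only, and 29 were unmatched. Tables were joined by name and coordinates, since 3 differed in order, and 8 host entries that repeat the coordinates of another were left out of the tests. Of the nested lambda frames, nu3 in C and SII in S can share reads, while Rz1, within Rz, had 29 reads in the lysogen at 20 min where Rz had 4569. Sums over the listed frames came to 638289 to 1381299 reads per library, 93.3% to 100% of the reads that scaled the values. The rest lay outside the listed frames and was not analysed here, apart from its share.

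Values were scaled to the same total over host frames, so that the lambda share does not lower host genes, and log2 transformed with a pseudocount of 1.54 RPKM, the 5th percentile of values above 0. Frames above it in both libraries of at least 1 group were tested, 3875 host and 72 lambda frames. Limma 3.58.1 in R 4.3.3 (limma-trend, with trended and robust variance moderation) fitted 1 model of 10 groups of 2 libraries, with 10 residual and a median of 4.79 prior degrees of freedom. Each later time was compared with 0 min within a strain, the strains at each time, and the responses of the strains with each other (lysogen later minus 0 min, minus the same in the non-lysogen), 17 comparisons in all. Adjusted p is Benjamini-Hochberg over all 3947 frames of a comparison, and a gene was called when it was under 0.05. Log2 changes stand with their standard error, and levels are means of deposited RPKM with the SD of 2 libraries. With 2 against 2 libraries the smallest exact permutation p is 0.333, so no comparison rests on a permutation of libraries.

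Camera, from limma, tested 25 gene lists of at least 5 host genes in 13 comparisons with a preset correlation of 0.01. It was run again with an estimated correlation, and p was adjusted over the lists of a comparison. Camera sets a list against the other host genes, so a list can be called lower without falling, or higher without rising. The lists were sigma32 heat shock, sigmaE and Cpx envelope stress, phage shock, cold shock, SOS, ribosomal proteins, RNA polymerase and translation factors, and stationary phase and acid stress. Others were ATP synthase, TCA cycle, flagella, maltose, cell division, host factors used by lambda and both flanks of attB. Biosynthesis lists covered arginine, methionine, leucine and isoleucine-valine, tryptophan and histidine, cysteine, purine and pyrimidine. The last list held cryptic prophage genes, of which 15 have a lambda counterpart listed by gene name and 17 do not. A rule named the 5 genes with the largest change per direction and time (10 at 0 min) among called genes of the upper 75% by mean whose libraries did not overlap between groups, up to 4 members per list, and 18 genes fixed in advance. The values of 1 of these genes are not reported here. Genes named outside it, among them those of the lambda classes, were chosen after their values were seen. A gene with 0 reads in a group was compared with 3 reads over the group, and one with 1 to 3 reads is given as a ratio with an exact 95% interval.

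The method was tested on data simulated from library depths (3923 genes, dispersion 0.05, 50 genes changed per size). In the simulated comparison of the non-lysogen at 5 and 0 min it called 18% of genes raised 2-fold and 88% of those raised 4-fold. It called 28% and 82% of those lowered as much, and 5 unchanged among 113 called. A simulated comparison without change, of the non-lysogen at the last time and 0 min, gave 0 calls. These rates hold for the simulated dispersion, and whether they carry over to the spread of these libraries or to genes with few reads was not tested. Alternatives were centring on the median gene, the authors' own scaling, no filter, a pseudocount 10 times larger or smaller, only the groups of a comparison in the fit, a replicate block, an adjusted p under 0.01, a change of at least 1 on the log2 scale, scaling over all frames, each library left out, and, chosen after seeing the data, voom on recovered reads. Log-scale correlations between replicates were 0.958 to 0.976. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.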

Results

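Ribosome profiling, the sequencing of mRNA fragments protected by ribosomes, was done on Escherichia coli MG1655 and on a lysogen of this strain that carries the prophage lambda cI857, whose repressor CI loses activity with heat. Cultures of both strains were shifted from 32 °C to 42 °C and sampled at 0 min, before the shift, and at 2, 5, 10 and 20 min, with 2 libraries per strain and time and 20 libraries in all. The values were ribosome densities (RPKM) of 4154 host and 73 lambda reading frames. Reads recovered from the values came to 646102 to 1430328 per library over all features counted, with 438857 to 1312075 in host frames. The frame with the most reads, lpp, which encodes the major outer membrane lipoprotein, took 3.59% to 9.91% of them. No label says that the replicates were separate cultures, so the p-values measure only the spread between these samples. The comparisons, gene lists and rule for naming genes were chosen before the data were examined. The design named a count-based test, and limma-trend in case the values were not read counts. Intervals and floors cover counting error only.

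The comparison at 0 min asked how the strains differed before the shift. The lysogen had ribosomes on cI, which encodes the repressor, at 267.6 ± 19.6 RPKM (SD, n = 2), where the non-lysogen had 0.883 ± 1.25. The frames next to cI, rexA and rexB, whose products exclude other phages, had 536.8 ± 94.1 and 358.9 ± 39.2 RPKM against 5.32 ± 5.21 and 1.58 ± 2.23. These frames and ea59, with 106.2 ± 18.2 RPKM against 1.63 ± 1.08, were the 4 of 72 lambda frames called higher in the lysogen, with adjusted p = 4.83e-05 for cI and rexA, 1.25e-06 for rexB and 3.01e-05 for ea59. Adjusted over the list alone, 9 were called. Of 3875 host genes, limma called 1, pspD of the phage shock operon, which lay at 14.97 ± 6.63 RPKM in the lysogen and 56.98 ± 24.4 in the non-lysogen (log2 difference -1.82 ± 0.31, SE, adjusted p = 0.0221). Voom called 0, and 160 had an unadjusted p under 0.05, fewer than that threshold passes on average when nothing differs. The call of pspD ended without lysogen replicate 1 or non-lysogen replicate 2 of 0 min, with the larger pseudocount, with only these groups in the fit and with voom, where its adjusted p reached 0.906. The count was 12 without non-lysogen replicate 1 and 2 without its replicate 2. No gene list was called at 0 min, except with a replicate block.

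The lambda frames of the lysogen were followed over time to describe how translation of the phage proceeded after the shift. Lambda took 0.113 ± 0.014% of the summed RPKM at 0 min, 1.41 ± 0.04% at 2 min, 20.4 ± 0.80% at 5 min, 24.9 ± 0.12% at 10 min and 29.6 ± 2.72% at 20 min (SD, n = 2). In the non-lysogen, which has no prophage, the share was 0.0242 ± 0.0189% at 0 min and at most 0.126 ± 0.0101%, at 10 min. At 0 min, 60.7% of the lambda reads of the lysogen lay in the immunity genes cI, rexA and rexB, and at 5 min 0.0846% did.

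**Figure D1:**
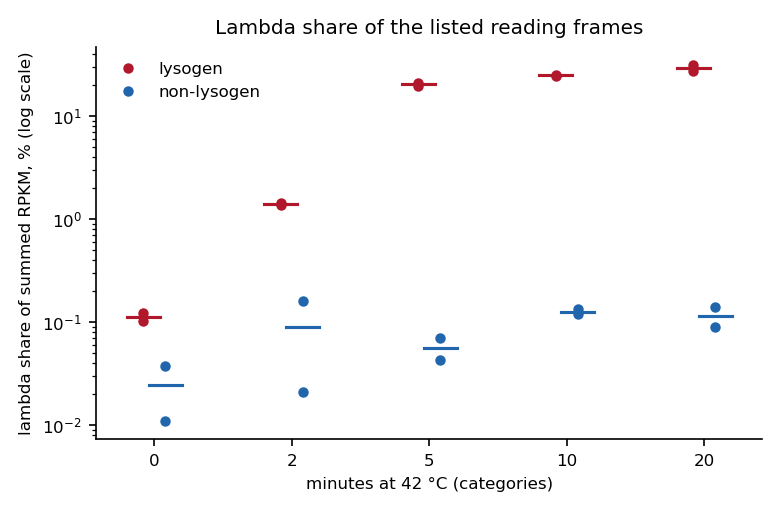
Share of the summed RPKM taken by lambda frames (percent, log axis) at 0, 2, 5, 10 and 20 min in the lysogen and the non-lysogen, with a dot per library and a bar at the mean of 2 libraries. The lysogen goes from 0.113% to 29.6%, and the non-lysogen libraries lie between 0.0108% and 0.158%.

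N and cro, which flank the immunity genes, were among the frames called at 2 min. N, the antitermination factor of the early operons, was at 49.0 ± 0.251 RPKM at 0 min and 9139 ± 65.8 at 2 min (log2 change 7.51 ± 0.45, SE, adjusted p = 1.99e-07), and 19510 ± 110 at 5 min. Cro, the repressor of the lytic phase, rose from 65.0 ± 15.2 RPKM to 5207 ± 154 at 2 min (6.32 ± 1.15, adjusted p = 0.00341) and 22520 ± 890 at 10 min. In the early left operon, whose products act in recombination and excision, ea10 reached 88520 ± 14700 RPKM, gam 45740 ± 3340, cIII 42170 ± 2700 and xis 38430 ± 1380 at 5 min. In the early right operon cII, O and P peaked at 10 min with 17590 ± 310, 12070 ± 587 and 6234 ± 834 RPKM, where O and P start lambda DNA replication. Q, the antitermination factor of the late operon, was at 4.45 ± 1.12 RPKM at 0 min and 13280 ± 826 at 10 min (11.52 ± 1.06, adjusted p = 3.58e-06). The non-lysogen had 10.6 ± 3.63 RPKM of Q at 0 min, so this starting level did not exceed background. Translation of cI fell from 267.6 RPKM to 26.1 ± 1.89 at 5 min (-3.02 ± 0.67, adjusted p = 0.0022) and that of rexA to 36.5 ± 5.66 (-3.56 ± 0.64, adjusted p = 0.000437). RexB, on the other hand, rose to 1396 ± 117 RPKM at 20 min (2.54 ± 0.48, adjusted p = 0.00049). The calls of cI and rexA ended with the smaller pseudocount, where 0 lambda frames were lower at 5 min. Q at 2 min, with 101.9 ± 7.06 RPKM and an adjusted p of 0.0214, lost its call without any 1 of its 4 libraries. The other calls in this paragraph with an adjusted p were kept with any 1 of the 4 libraries of their comparison left out. Standard errors pool the spread of all 10 groups, so the background reads of the non-lysogen enter them. Gam rose from 15.7 ± 3.65 to 867.3 ± 18.3 RPKM in the lysogen at 2 min, with a log2 change of 5.69 ± 1.52. In the non-lysogen gam was at 40.8 ± 57.7 RPKM at 0 min and 109.9 ± 134 at 2 min. The adjusted p of a lambda frame thus does not measure the spread of the lysogen libraries alone.

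The late genes came last and were still increasing at 20 min. D and E, the capsid proteins, went from 376.5 ± 76.3 and 109.9 ± 5.52 RPKM at 5 min to 7238 ± 3110 and 3684 ± 1660 at 10 min and 52190 ± 7940 and 36810 ± 5540 at 20 min. D had 2 reads at 0 min and 28803 at 20 min, a depth-corrected ratio of 28260 (95% interval 7822 to 233300). The non-lysogen had 7 reads of D at 0 min, so the starting level did not exceed background. The tail genes G, U and V were at 29190 ± 6110, 25370 ± 3860 and 22500 ± 3810 RPKM at 20 min, where J, the tail fibre gene, was at 1878 ± 128. Of the lysis genes, R, the endolysin, reached 10070 ± 1790 RPKM and S, the holin, 1751 ± 217. The frame nu1, the small terminase subunit, had 0 reads at 0 min and was at least 114-fold higher at 20 min. By class, the median over early left genes was 14700 RPKM at 5 min and 4650 at 20 min, that over early right genes was 9559 at 10 min, and that over head and tail genes went from 2188 and 287.6 at 10 min to 9378 and 3195 at 20 min.

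**Figure D2:**
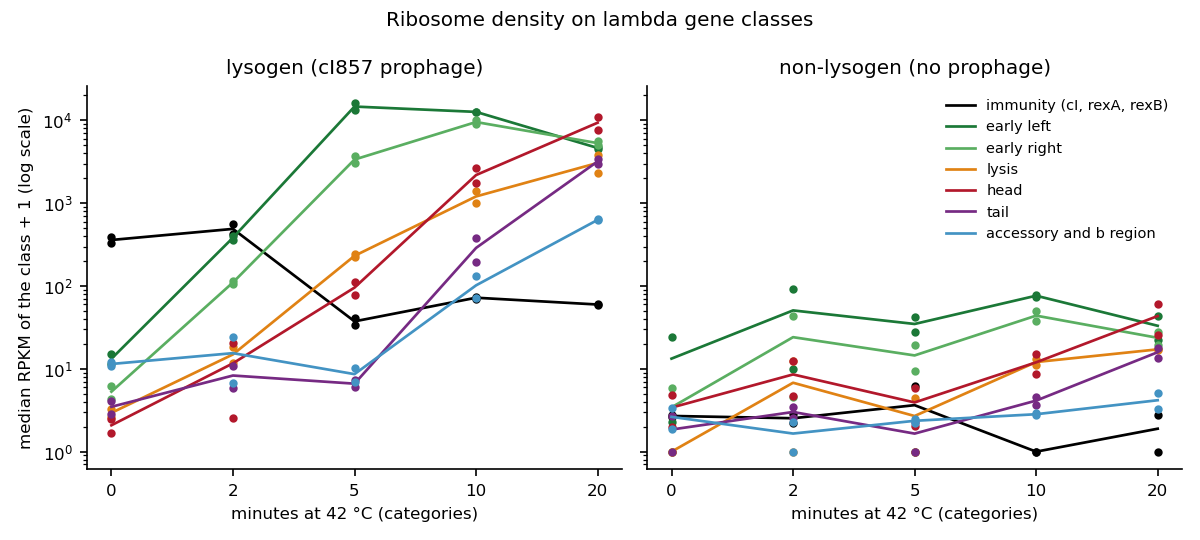
Median RPKM + 1 (log axis) of the genes of each lambda class against time after the shift, in the lysogen (left) and the non-lysogen (right), with points for libraries and lines through the mean of 2. Early left genes are highest at 5 min (14700 RPKM), early right genes at 10 min (9559) and head genes at 20 min (9378).

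Limma called 29 of 72 lambda frames higher at 2 min, 53 higher and 4 lower at 5 min, 67 higher and 2 lower at 10 min and 70 higher and 2 lower at 20 min, against 0 min. Adjusted over the list alone, these were 37 at 2 min, 53 and 4 at 5 min, 68 and 2 at 10 min and 70 and 2 at 20 min. Called at 2 min were 9 of 12 early left, 13 of 14 early right and 1 of 7 accessory genes. The class named lysis holds S, R, Rz and Rz1, and also bor, which is not a lysis gene. In this class 1 of 5, Rz, was called, and 0 of 10 head, 11 tail and 3 immunity genes were. At 5 min 12 of 12 early left, 14 of 14 early right, 9 of 10 head and 6 of 11 tail genes were called higher. So were 3 of 5 in the lysis class, S, R and Rz. At 20 min all members of these 5 classes and 7 of 7 accessory genes were called higher. Of the 3 immunity genes, 2, cI and rexA, were called lower at 5, 10 and 20 min. With the smaller pseudocount 47, 64 and 67 frames were higher at these times and 0 lower, and without lysogen replicate 2 of 20 min the adjusted p of cI at 20 min was 0.0892. The count at 2 min was 17 without lysogen replicate 1 of 0 min or replicate 2 of 2 min, 19 without replicate 2 of 0 min and 19 with the smaller pseudocount. Lysogen replicate 2 of 2 min carried more late reads than replicate 1, so that D lay at 64.1 ± 77.5 and E at 41.3 ± 57.0 RPKM at that time.

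Lambda frames also had reads in the non-lysogen, 83 to 1457 per library, which sets the background of every lambda value. Among them were N, at 23.9 ± 19.4 RPKM at 0 min and 88.2 ± 4.91 at 10 min, and ea10, at 89.6 ± 100 RPKM at 0 min. Against 0 min, limma called 5, 5, 23 and 28 of 72 lambda frames in the non-lysogen at 2, 5, 10 and 20 min (2, 2, 22 and 31 adjusted over the list alone). Set against the non-lysogen at the same time, the lysogen had 9 frames called at 2 min, 50 at 5 min and 72 at 10 and at 20 min (34, 64, 72 and 72 adjusted over the list alone).

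The time course of the non-lysogen showed the changes that followed the temperature shift without a prophage. No library came from a culture kept at the starting temperature for as long. Heat was therefore not separated from time in culture or handling. Of the heat shock genes of sigma32, which encode chaperones and proteases, 17 of 27 were higher at 2 min. IbpB and ibpA, small chaperones of aggregated proteins, went from 124.3 ± 94.3 and 243.4 ± 34.6 RPKM at 0 min to 4983 ± 554 and 7530 ± 958 at 2 min and 51110 ± 6390 and 47270 ± 140 at 5 min (log2 change at 5 min 8.90 ± 0.68, adjusted p = 1.31e-06, and 7.60 ± 0.32, adjusted p = 3.44e-10). The disaggregase clpB rose by 4.56 ± 0.15 at 5 min (adjusted p = 1.35e-11) and dnaK, the main Hsp70 chaperone, from 1260 ± 50.5 to 19120 ± 1680 RPKM (3.92 ± 0.17, adjusted p = 1.47e-10). GroL, the chaperonin subunit, was highest at 10 min with 29460 ± 2790 RPKM against 1884 ± 69 (3.96 ± 0.13, adjusted p = 1.25e-11). At 20 min ibpB was at 232.3 ± 83.5 RPKM (1.09 ± 0.68, adjusted p = 0.248), whereas groL was still 2.58 ± 0.13 above 0 min. RpoH, which encodes sigma32 itself, rose by 1.26 ± 0.11 at 2 min and 2.40 ± 0.11 at 10 min. Of the 27 listed sigma32 genes, 17, 24, 25 and 19 were called higher at 2, 5, 10 and 20 min and 0 lower (adjusted over the list alone 18, 25, 25 and 19 higher and, at 2 min, 1 lower). Camera gave adjusted p = 3.2e-11, 5.07e-24, 2.04e-14 and 1.21e-08. These were adjusted p = 0.0997, 0.0411, 0.0358 and 0.143 with an estimated correlation.

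**Figure D3:**
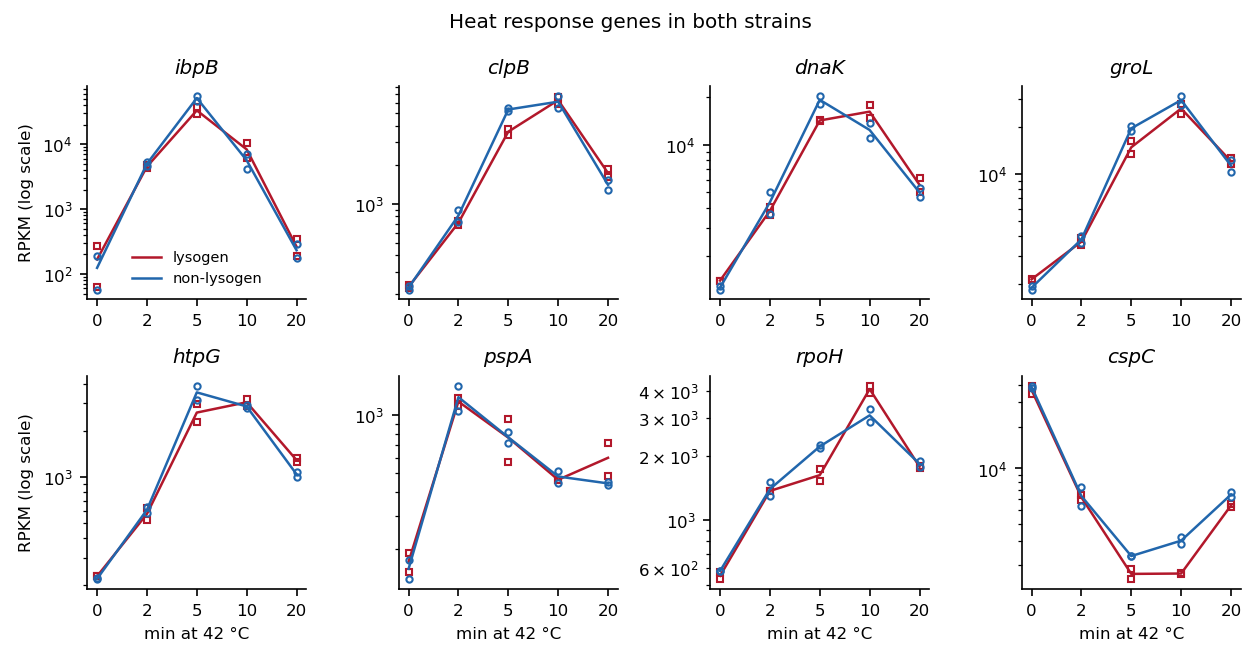
RPKM (log axis) of ibpB, clpB, dnaK, groL, htpG, pspA, rpoH and cspC against time after the shift, with red squares for lysogen and blue circles for non-lysogen libraries. In the non-lysogen dnaK goes from 1260 RPKM at 0 min to 19120 at 5 min, and cspC from 38930 to 2331.

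Most genes of the phage shock operon and of methionine biosynthesis were higher at 2 min as well. The phage shock operon, which responds to damage of the inner membrane, had 5 of 6 genes higher at 2 min, with pspC at 570.7 ± 71.5 RPKM against 43.89 ± 2.67 (log2 change 3.65 ± 0.20, adjusted p = 1.46e-08) and pspA at 1239 ± 262 against 158.3 ± 26.5 (2.95 ± 0.25, adjusted p = 1.49e-06). Its calls were 5 higher at 5 min, 4 higher and 1 lower at 10 min and 5 higher at 20 min (adjusted over the list alone 5, 5, 5 and 1 lower, and 5). With centred scaling 3 were higher and 1 lower at 20 min. Camera gave adjusted p = 1.67e-07, 0.00106, 0.0422 and 0.036, which were adjusted p = 0.0416, 0.125, 0.233 and 0.248 with an estimated correlation. Of 10 methionine biosynthesis genes, whose first enzyme MetA is unstable in heat, 8, 7, 7 and 6 rose, and 1 fell at 10 and at 20 min (adjusted over the list alone 8, 8, 7 and 6 higher, 1 lower at 10 and 20 min). MetB went from 105.8 ± 0.777 to 631.1 ± 61.1 RPKM at 2 min (2.56 ± 0.30, adjusted p = 4.07e-05) and metA from 171.9 ± 28.4 to 1088 ± 199 at 10 min (2.65 ± 0.20, adjusted p = 7.08e-08). Camera gave adjusted p = 3.81e-07, 3.16e-05, 0.00239 and 0.021 for this list, and adjusted p = 0.0851, 0.125, 0.184 and 0.311 with an estimated correlation. CpxP, a target of the Cpx envelope stress system, rose by 1.90 ± 0.26 at 2 min and 3.23 ± 0.26 at 10 min, while the 9 Cpx genes gave 3 higher and 1 lower, 5 and 2, 5 and 0, and 5 and 1 (adjusted over the list alone 3 and 1, 5 and 2, 5 and 1, 5 and 1, and 5 and 2 at 10 min with centred scaling) without a camera call at any time (adjusted p = 0.399, 0.084, 0.0571 and 0.0521).

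Some cold shock genes fell, as did most genes of arginine, pyrimidine, purine and cysteine biosynthesis at 10 min. CspC, an abundant member of the cold shock protein family, dropped from 38930 ± 1130 to 6323 ± 1390 RPKM at 2 min and 2331 ± 16.2 at 5 min (log2 change -4.06 ± 0.14, adjusted p = 1.43e-11). The RNA helicase gene deaD fell by 2.20 ± 0.25 at 2 min. The 13 cold shock genes had 4, 6, 4 and 4 members lower and 1 higher at each time, also adjusted over the list alone, and camera gave adjusted p = 0.00121, 0.0172, 0.0723 and 0.00104, with adjusted p = 0.223, 0.246, 0.394 and 0.169 with an estimated correlation. CarB, which feeds the arginine and pyrimidine pathways, went from 805.5 ± 57.2 to 28.35 ± 2.02 RPKM at 10 min (-4.75 ± 0.26, adjusted p = 2.38e-09). The arginine gene argF went from 1044 ± 51.4 to 48.81 ± 14.6 (-4.41 ± 0.30) and pyrB from 4953 ± 157 to 479.6 ± 103 RPKM (-3.38 ± 0.32). At 10 min, 10 of 11 arginine, 9 of 10 pyrimidine, 13 of 14 purine and 11 of 11 cysteine genes fell and 0 rose, and 11, 9, 13 and 11 did so adjusted over the list alone. Camera called these 4 lists lower at 10 min (adjusted p = 1.43e-10, 2.6e-09, 9.95e-12 and 4.81e-10), each with adjusted p = 0.0358 with an estimated correlation. At 20 min 11 arginine and 8 pyrimidine genes were lower, and both calls held with an estimated correlation (adjusted p = 0.0359). The cysteine list instead had 7 of 11 genes higher at 20 min, cysA among them with 449.3 ± 50.7 RPKM against 159.2 ± 0.488 (8 adjusted over the list alone, 2 with centred scaling, camera adjusted p = 0.021). That list had adjusted p = 0.349 with an estimated correlation.

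Most listed genes of the TCA cycle and the ribosome were lower at 5 min. SdhA, a subunit of succinate dehydrogenase, went from 533.2 ± 38.6 to 58.22 ± 7.73 RPKM at 5 min (log2 change -3.17 ± 0.19, adjusted p = 9.23e-09), and sucC of the same cycle fell by 2.45 at 10 min (-2.45 ± 0.13, adjusted p = 2.64e-09). Of 15 TCA cycle genes, 4, 13, 13 and 12 fell at 2, 5, 10 and 20 min, and 1 rose at 10 and 20 min (adjusted over the list alone 4, 13, 14 and 12 lower). Of 8 ATP synthase genes, 0, 7, 8 and 7 fell (0, 7, 8 and 8 adjusted over the list alone, and 4 at 5 min with centred scaling), with atpE at 3340 ± 256 RPKM at 10 min against 7715 ± 496. Camera gave adjusted p = 0.000297, 4.75e-08, 8.73e-11 and 1.38e-12 for the cycle and 0.664, 0.0188, 1.52e-06 and 1.67e-06 for the synthase. With an estimated correlation both had adjusted p = 0.0358 at 10 min and 0.0359 at 20 min, against 0.304 and 0.852 at 2 min and 0.125 and 0.189 at 5 min. Of 54 ribosomal protein genes, 37 fell and 1 rose at 5 min, with rpsA at 664.9 ± 27.2 RPKM against 2292 ± 262 (-1.78 ± 0.15, adjusted p = 3.7e-07). At 10 min 32 fell and 1 rose, rplB from 3351 ± 240 to 535 ± 90.1 RPKM, and adjusted over the list alone 38 and 33 fell. Camera gave adjusted p = 2.44e-09 and 1.82e-11, which became adjusted p = 0.137 and 0.0778 with an estimated correlation. At 2 min 9 were higher and 3 lower, 4 and 3 with centred scaling (camera adjusted p = 0.965). At 20 min 6 were higher and 7 lower, a split that became 0 and 20 with centred scaling. The list's median was 0.02 and its mean -0.01, where the median of all host genes was 0.36. Camera called the list lower relative to the other host genes (adjusted p = 0.036). That call had adjusted p = 0.496 with an estimated correlation. RaiA and bolA, of the stationary phase list, rose by 2.69 ± 0.23 and 2.36 ± 0.13 at 10 min, when 12 of its 21 genes were higher and 1 lower (12 and 2 adjusted over the list alone, 8 and 4 with centred scaling, camera adjusted p = 0.0213). That list had adjusted p = 0.416 with an estimated correlation.

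The remaining lists are given mainly at 20 min. The biofilm and acid resistance gene ariR rose from 28.74 ± 26.1 to 2482 ± 1230 RPKM (log2 change 6.60 ± 0.56, adjusted p = 1.94e-06), and its neighbour ymgC, with 0 reads at 0 min, was at least 23.4-fold higher. GlnA, glutamine synthetase, fell from 2763 ± 56.9 to 169 ± 17.7 RPKM (-4.02 ± 0.12, adjusted p = 6.21e-12) and nac, a regulator of nitrogen limitation, from 158.6 ± 10.6 to 5.47 ± 2.10 (-4.55 ± 0.28, adjusted p = 1.89e-08). LamB, the receptor of lambda, had 1 read at 20 min and 115 at 0 min, a ratio of 121 (95% interval 21.3 to 4825). The maltose list, with lamB, had 5 of 10 members lower, flagella 8 of 27 lower and 1 higher, tryptophan and histidine 5 of 13 lower, purine 7 of 14 lower and 2 higher, leucine and isoleucine-valine 5 of 13 lower and 3 higher (5, 9, 5, 8 and 7 lower adjusted over the list alone). With centred scaling tryptophan and histidine had 8 lower and purine 9 lower and 0 higher. Camera called these lower (adjusted p = 0.00017, 0.000431, 0.00019, 0.00104 and 0.036), with adjusted p = 0.106, 0.171, 0.237, 0.171 and 0.349 with an estimated correlation. The bio side of the phage attachment site attB had 9 of 16 genes higher (10 adjusted over the list alone, 5 with centred scaling, camera adjusted p = 0.021), with adjusted p = 0.171 with an estimated correlation. Camera called no other list: sigmaE genes had 4 of 16 higher and 2 lower, which turned to 3 and 5 with centred scaling, SOS genes 5 of 27 higher and 2 lower, which turned to 2 and 5, and the gal side of attB 3 of 16 higher, which turned to 2 higher and 3 lower. RNA polymerase and translation factors had 3 of 15 higher and 3 lower, cell division 6 of 16 higher, host factors used by lambda 8 of 21 higher and 1 lower, and cryptic prophage genes 8 of 32 higher (adjusted over the list alone 3 and 3, 7, 8 and 1, and 8). Centred scaling gave 0 and 6 for the polymerase and translation factors and 4 higher cryptic prophage genes. Some of these lists differed at earlier times. RNA polymerase and translation factors had 11 lower at 5 min and 8 at 10 min, with 0 higher (camera adjusted p = 0.000273 and 0.000573), and tryptophan and histidine 10 of 13 lower at 10 min (camera adjusted p = 1.05e-05). With an estimated correlation these had adjusted p = 0.144, 0.175 and 0.175. SigmaE had 2 higher and 8 lower at 5 min and 3 and 8 at 10 min, without a camera call (adjusted p = 0.0767 and 0.154).

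Across all 3875 host genes of the non-lysogen, limma called 419 higher and 235 lower at 2 min, 639 and 857 at 5 min, 981 and 653 at 10 min and 950 and 342 at 20 min. These changes are relative to the host total of each library. Centring on the median gene moved the median change from 0.24 to 0.02 at 10 min and from 0.36 to 0.01 at 20 min, and gave 337 higher and 307 lower at 2 min, 750 and 845 at 10 min and 563 and 600 at 20 min. The 654 calls at 2 min were 368 without replicate 2 of 0 min, 289 without replicate 1 of 2 min and 435 without replicate 2 of 2 min. The 1292 at 20 min were 849 without replicate 1 of that time.

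The same times in the lysogen asked how much of the host response was shared. Limma called 400 genes higher and 214 lower at 2 min, 547 and 860 at 5 min, 867 and 882 at 10 min and 937 and 595 at 20 min. At 5 min 433 genes were higher in both strains, where independent calls would share 90.2, and 689 were lower in both, where they would share 190. Those called in opposite directions numbered 0, 2, 7 and 29 at 2, 5, 10 and 20 min. The log2 changes of the strains had Pearson correlations of 0.68, 0.79, 0.81 and 0.64 across genes, which are not independent replicates. ClpB reached 6326 ± 544 RPKM in the lysogen and 6156 ± 979 in the non-lysogen at 10 min, and cspC lay at 6192 ± 368 and 6323 ± 1390 at 2 min. These levels count lambda in the total, while the log2 changes are scaled to the host total. That scaling multiplies the lysogen libraries by 1.305 and 1.318 at 10 min and by 1.011 at 2 min, and the non-lysogen ones at 10 min by 1.001. On the host scale clpB was therefore higher in the lysogen at 10 min. The directions depended on the scaling: with values as the authors scaled them, which include lambda in the total, the lysogen gave 399 higher and 1164 lower at 5 min, 586 and 1180 at 10 min and 522 and 1092 at 20 min. Centring gave 308 higher of 622 called at 2 min and 738 higher and 806 lower at 20 min. The 614 calls at 2 min were 342 without replicate 2 of 0 min, 378 without replicate 1 of 2 min and 356 without replicate 2 of 2 min. Camera called 10, 13, 17 and 16 lists in the lysogen, and 1, 1, 9 and 9 with an estimated correlation.

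The difference between the responses of the strains, an interaction, separated what followed induction of the prophage from changes shared with the non-lysogen. At 2 min limma called 0 of 3875 host genes, with 97 at an unadjusted p under 0.05 and 0 by voom, and the count was 2 without non-lysogen replicate 2 of 0 min. On average a threshold of 0.05 passes more genes than these 97 when nothing differs, and more than the 82 given below for the strains at 2 min. The counts of 0 thus do not show that the strains were alike. No list was called. At 5 min 6 genes were called, fewer than with a replicate block, and 3 of the 6 lay beside attB on the gal side. YbhC, which encodes an outer membrane lipoprotein, had 1843 ± 576 RPKM in the lysogen against 111.5 ± 0.961 at 0 min, and 73.67 ± 7.97 in the non-lysogen (log2 difference 5.59 ± 0.28, adjusted p = 1.57e-08). YbhD, a predicted regulator, had 332.4 ± 79.2 RPKM against 1.77 ± 0.883 at 0 min (adjusted p = 0.000373, and 0.213 with the smaller pseudocount), and ybhA, a phosphatase gene, 132.5 ± 34.8 (1.77 ± 0.33, adjusted p = 0.0178). CpxP was at 2291 ± 792 RPKM in the lysogen and 496.2 ± 121 in the non-lysogen (2.39 ± 0.37, adjusted p = 0.00284). Ssb, the single-strand DNA binding protein, was higher by 0.92 ± 0.19 (adjusted p = 0.0314) and yjdK lower (adjusted p = 0.0445), and across the settings and left-out libraries the adjusted p reached 0.206 and 0.715, and 0.103 for ybhA. The calls of these 3 ended without replicate 1 or 2 of the non-lysogen at 0 or 5 min and without lysogen replicate 2 of 0 min. That of ssb and yjdK also ended without lysogen replicate 1 of 0 min, that of ybhA and ssb without lysogen replicate 2 of 5 min and under the authors' scaling, and that of yjdK without lysogen replicate 1 of 5 min. The count of 6 was 17 without non-lysogen replicate 1 of 0 min and 3 without non-lysogen replicate 1 or 2 of 5 min.

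Among the lists at 5 min, the gal side of attB had 3 of 16 genes higher, also adjusted over the list alone, with camera adjusted p = 6.44e-06, and adjusted p = 0.00938 with an estimated correlation. The other camera calls at 5 min did not keep a call under it. Cpx had 1 of 9 higher (2 adjusted over the list alone, camera adjusted p = 6.44e-06), with adjusted p = 0.254 with an estimated correlation. For the arginine and cysteine lists, with 0 members called, medians of 0.63 and 0.40 and camera adjusted p = 5.58e-05 and 0.000835, it was adjusted p = 0.483 and 0.554 with an estimated correlation. The sigma32, ribosomal, tryptophan and histidine, and purine lists, with 0 members called, had medians of -0.27, -0.18, 0.21 and 0.18 and camera adjusted p = 0.00143, 0.0326, 0.0271 and 0.0278, each with adjusted p = 0.688 with an estimated correlation.

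At 10 min genes of the galactose operon and most Cpx genes were higher in the lysogen by this difference. GalK, galactokinase, was at 805.9 ± 65.1 RPKM in the lysogen against 47.46 ± 8.11 at 0 min, and at 42.71 ± 6.28 in the non-lysogen (log2 difference 4.61 ± 0.30, adjusted p = 4.09e-07). GalT rose likewise (4.16 ± 0.41, adjusted p = 2.29e-05), and ybhC was at 4.91 ± 0.28 (adjusted p = 9.84e-08). The gal side had 8 of 16 genes higher (9 adjusted over the list alone, camera adjusted p = 1.05e-20, and adjusted p = 3.96e-05 with an estimated correlation). CpxP reached 9053 ± 967 RPKM in the lysogen and 801.8 ± 80.6 in the non-lysogen (3.82 ± 0.37, adjusted p = 1.87e-05). The periplasmic protease gene degP reached 2811 ± 124 and 614.5 ± 8.04 (2.76 ± 0.26, adjusted p = 1.85e-05), and the membrane protease gene htpX 4032 ± 113 and 1185 ± 79.7 (2.17 ± 0.24, adjusted p = 5.13e-05). Of 9 Cpx genes 6 were higher and 0 lower, also adjusted over the list alone, with camera adjusted p = 1.04e-14, and adjusted p = 0.016 with an estimated correlation. SigmaE, the other envelope stress list, had 1 of 16 higher and 1 lower, with a median of -0.09 (1 and 3 adjusted over the list alone, camera adjusted p = 0.913). RaiA, which inactivates ribosomes in stationary phase, was at 32380 ± 2860 RPKM in the lysogen and 8069 ± 1350 in the non-lysogen (2.31 ± 0.32, adjusted p = 0.000364). Ssb was higher by 1.72 ± 0.19 (adjusted p = 4.64e-05) and dinD, an SOS gene, by 2.94 ± 0.46 (adjusted p = 0.00112). YagU, an inner membrane protein, fell to 16.03 ± 11.6 RPKM in the lysogen and was at 254 ± 6.93 in the non-lysogen (-3.60 ± 0.58, adjusted p = 0.00183). Uof, the leader frame of fur, had 0 reads in the lysogen at 10 min, at least 7.70-fold fewer than at 0 min (adjusted p = 0.000526, and 0.0563 by voom).

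Limma called 53 host genes higher and 61 lower at 10 min, fewer in all than with a replicate block. These were 66 and 22 with centred scaling and 46 and 533 as the authors scaled the values, which moved the median of the differences from -0.20 to -0.55, and from -0.07 to -0.32 at 5 min and -0.15 to -0.67 at 20 min. The 114 calls were 68 without lysogen replicate 2 of 0 min, 74 without non-lysogen replicate 2 of 0 min and 71 without non-lysogen replicate 2 of 10 min. The rule also named yncJ (3.89 ± 0.87), ydhO (-3.15 ± 0.72), flhD (-3.03 ± 0.72) and ccmG, whose adjusted p of 0.0214, 0.0183, 0.0244 and 0.0406 reached 0.212, 0.087, 0.123 and 0.169 across the settings and left-out libraries. Without replicate 2 of 10 min of either strain all 4 calls ended, and for 1 or more of them also without any of the other 6 libraries. Sigma32 genes had 3 of 27 higher (6 adjusted over the list alone, 7 with centred scaling, camera adjusted p = 5.96e-13), with adjusted p = 0.0759 with an estimated correlation. ATP synthase had 3 of 8 lower, 1 with centred scaling, atpC among them (-1.11 ± 0.22, adjusted p = 0.00721), and leucine and isoleucine-valine 1 of 13 lower (5 and 8 adjusted over the list alone, camera adjusted p = 4.82e-05 and 5.83e-05), with adjusted p = 0.0672 and 0.138 with an estimated correlation. Ribosomal proteins had 4 of 54 lower, 0 with centred scaling (9 adjusted over the list alone, camera adjusted p = 0.000848), with adjusted p = 0.518 with an estimated correlation. The TCA and cysteine lists had 1 member lower each and tryptophan and histidine 0 (camera adjusted p = 0.00329, 0.00568 and 0.0201), with adjusted p = 0.484, 0.484 and 0.597 with an estimated correlation. As the authors scaled the values, ATP synthase had 7 lower, leucine and isoleucine-valine 9, ribosomal proteins 25, TCA 8, cysteine 6, tryptophan and histidine 6 and sigmaE 4. SOS genes had 2 of 27 higher and a median of -0.10, where the median of all host genes was -0.20. Camera called the list higher relative to the other host genes (adjusted p = 0.0476), with adjusted p = 0.518 with an estimated correlation.

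At 20 min both sides of attB, the SOS genes and the branched-chain amino acid genes stood apart. GalT was at 360.1 ± 29.3 RPKM in the lysogen against 28.09 ± 1.40 at 0 min (log2 difference from the response of the non-lysogen 4.66 ± 0.41, adjusted p = 2.96e-06), with galK at 4.36 and ybhC at 4.08. On the bio side, bioB, biotin synthase, was at 1397 ± 360 RPKM in the lysogen and 367.1 ± 5.82 in the non-lysogen (2.73 ± 0.26, adjusted p = 6.15e-06). Both lists had 13 of 16 genes higher (15 and 14 adjusted over the list alone, camera adjusted p = 6.58e-26 and 2.16e-17). They held with adjusted p = 1.37e-05 and 0.000403 with an estimated correlation. The DNA repair gene recN was higher by 3.33 ± 0.36 (adjusted p = 2.49e-05). LexA, the SOS repressor, was at 1058 ± 8.34 RPKM against 256.6 ± 19.3 in the non-lysogen (2.84 ± 0.32, adjusted p = 3.08e-05), recA at 1621 ± 109 against 989.4 ± 47.2 (1.45 ± 0.17, adjusted p = 4.03e-05) and sulA, the inhibitor of division, at 305.9 ± 17.4 against 115 ± 7.14 (2.14 ± 0.28, adjusted p = 0.000122). Of 27 SOS genes 12 were higher and 0 lower (16 adjusted over the list alone, camera adjusted p = 4.15e-16, and adjusted p = 0.00563 with an estimated correlation). The SOS gene uvrB, also on the bio side list, was higher by 3.17 ± 0.28. FtsZ, which forms the division ring, fell to 651.2 ± 35.8 RPKM against 2246 ± 52.9 in the non-lysogen (-1.18 ± 0.16, adjusted p = 0.000122). The isoleucine and valine gene ilvC was at 515.6 ± 137 RPKM against 2538 ± 793 in the non-lysogen (-1.64), and ilvM was lower as well (-2.91 ± 0.46, adjusted p = 0.000572). Of the 13 genes of this list 10 were lower (11 adjusted over the list alone, camera adjusted p = 1.1e-09, and adjusted p = 0.0243 with an estimated correlation). These 4 lists were the camera calls at 20 min that held with an estimated correlation.

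**Figure D4:**
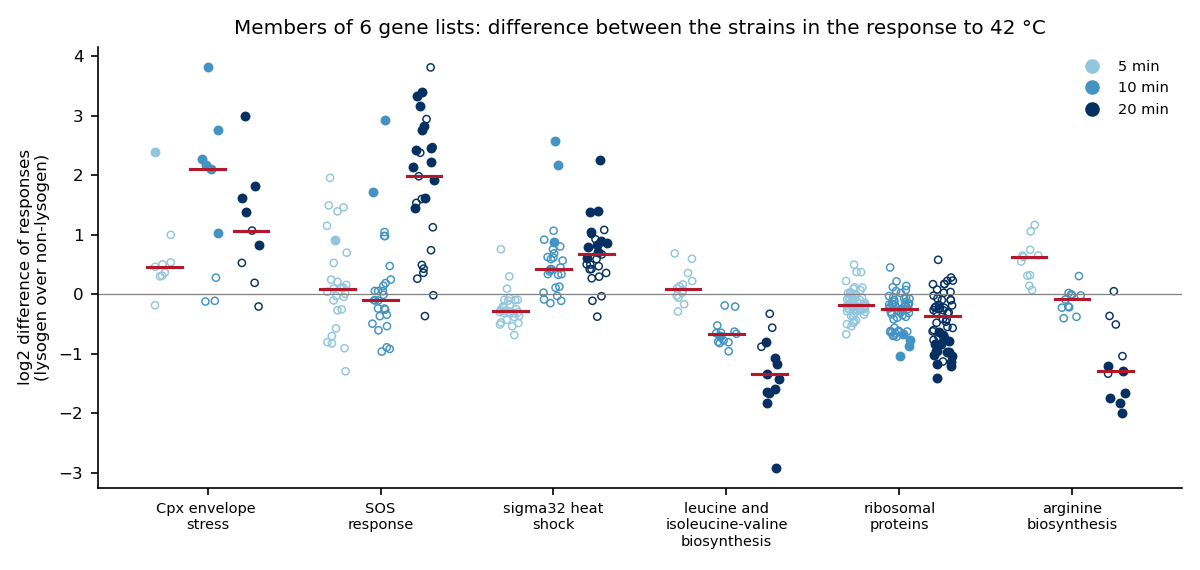
Log2 difference between the responses of lysogen and non-lysogen for the members of 6 gene lists at 5, 10 and 20 min, with filled points for genes called by limma and a red bar at the list median. The median of the SOS list is 1.99 at 20 min and -0.10 at 10 min, and that of the Cpx list is 2.12 at 10 min.

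Limma called 172 host genes higher and 258 lower at 20 min, 187 and 186 with centred scaling and 99 and 931 as the authors scaled the values, and 274 in all without lysogen replicate 2 of 0 min. Sigma32 genes had 10 of 27 higher and 0 lower, which was 3 and 3 as the authors scaled the values, and Cpx 5 of 9 higher, cpxP by 3.00 and degP by 1.82 (18 and 7 adjusted over the list alone, camera adjusted p = 9.13e-11 and 7.2e-07). Both lost the call, with adjusted p = 0.0847 and 0.0836 with an estimated correlation. Ribosomal proteins had 16 of 54 lower, rplV among them (-1.21 ± 0.19), arginine 6 of 11 lower, argG among them (-1.73 ± 0.21, adjusted p = 5.1e-05), and the stationary phase and acid list 7 of 21 lower and 1 higher, with hdeA at -1.38 ± 0.29 and gadE at -1.29 (18, 8 and 15 lower adjusted over the list alone, camera adjusted p = 6.72e-06, 5.03e-05 and 0.00033). These had adjusted p = 0.237, 0.211 and 0.267 with an estimated correlation. Cysteine had 2 of 11 lower, ATP synthase 3 of 8 lower, tryptophan and histidine 1 of 13 lower and purine 2 of 14 higher, which turned to 2 lower as the authors scaled the values (camera adjusted p = 0.000555, 0.00772, 0.00876 and 0.00252), with adjusted p = 0.237, 0.208, 0.398 and 0.237 with an estimated correlation. As the authors scaled the values, ribosomal proteins had 40 lower, the stationary phase and acid list 16, cysteine 8, ATP synthase 7 and tryptophan and histidine 11. Cryptic prophage genes had 7 of 32 higher and 2 lower (also adjusted over the list alone, camera adjusted p = 0.0183), with adjusted p = 0.292 with an estimated correlation, and among them tfaQ had 794 reads in the lysogen and 3 at 0 min, a ratio of 519 (95% interval 177 to 2524, and a call that ended with the smaller pseudocount, adjusted p = 0.0674). HisL, the leader peptide of the histidine operon, had 0 reads in the lysogen, at least 10.2-fold fewer than at 0 min (adjusted p = 0.0009). YagU was again lower in the lysogen (-3.15 ± 0.58). The rule also named gatB, with 3 reads in the lysogen and a ratio of 83.6 to 0 min (95% interval 28.4 to 406.7), dicC and ymgC, whose adjusted p of 0.0287, 0.0314 and 0.00922 reached 0.203, 0.149 and 0.176 across the settings and left-out libraries. The calls of gatB and dicC ended without any 1 of the libraries of 0 min or of the non-lysogen at 20 min, and that of ymgC without non-lysogen replicate 1 of 20 min.

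Distance from attB was examined because the prophage is inserted there, between the end of ybhC at 806504 and the start of ybhB at 806656 in the coordinates of the deposited values. On the gal side at 10 min, the 9 genes on the minus strand, which run in the direction of the left operon of the prophage, had a median difference of 3.21, and the 7 on the plus strand 0.59, a gap of 2.62 (2-sided exact permutation p = 0.0223). At 20 min the medians were 4.08 and 2.49. On the bio side the 12 plus-strand genes had a median of 0.13 at 10 min and 1.95 at 20 min, and the 4 minus-strand genes 0.61 and 1.87. Genes 20 to 100 kb from attB had medians of -0.08 (gal side, 61 genes) and 0.03 (bio side, 74 genes) at 10 min, and of 0.79 and 1.25 at 20 min. For 3702 genes farther away the median at 20 min was -0.18 (one-sided permutation p = 1e-05 for each side, the smallest that 100000 resamples can give). Genes are not independent replicates.

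**Figure D5:**
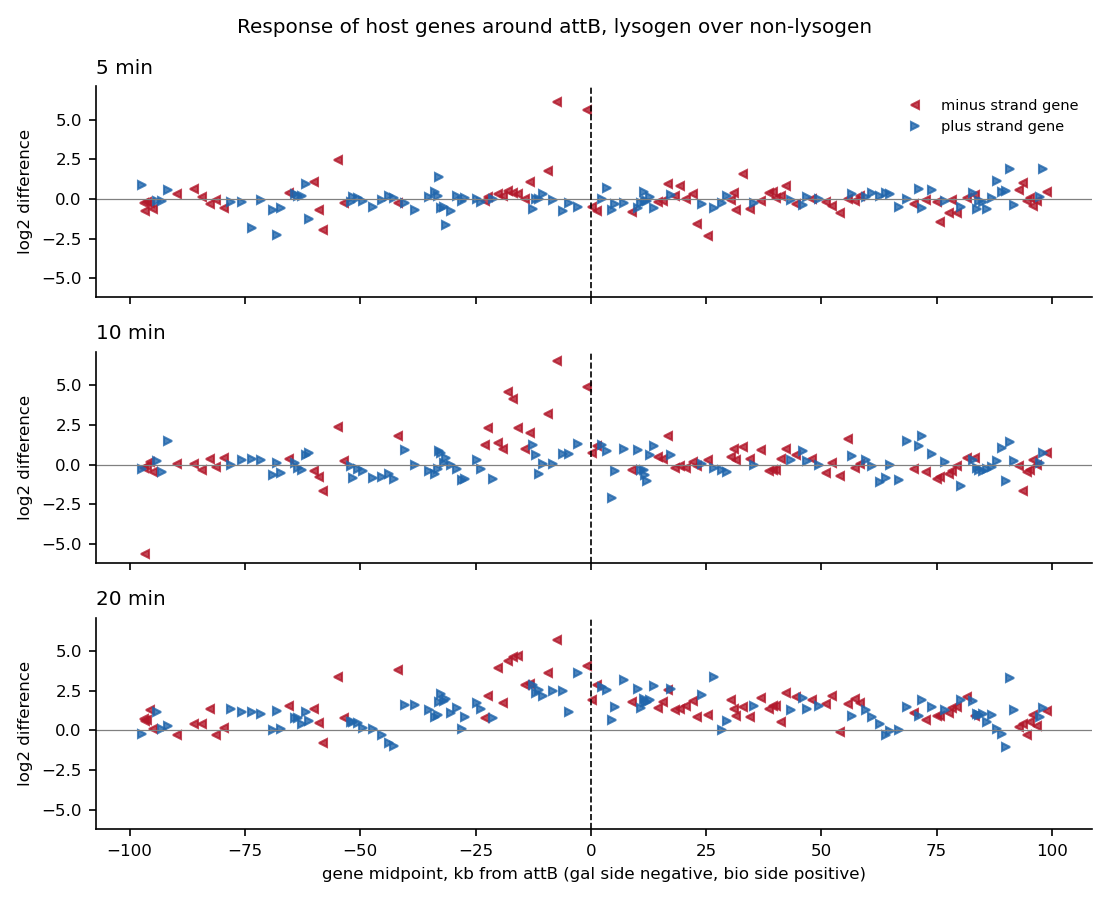
Log2 difference between the responses of lysogen and non-lysogen against distance from attB (kb) at 5, 10 and 20 min, with red left triangles for genes on the minus strand and blue right triangles for the plus strand. At 20 min the median is 2.88 within 20 kb on the gal side and 0.59 at 50 to 100 kb.

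Set directly against the non-lysogen at the same time, the lysogen had 0 host genes called by limma at 2 min, with 82 at an unadjusted p under 0.05 and 0 by voom, and 2 without non-lysogen replicate 1 of 2 min. At 5 min 7 were higher and 5 lower, 10 and 4 with centred scaling and 8 and 165 as the authors scaled the values, and 25 were called without lysogen replicate 2 of 5 min. At 10 min 97 were higher and 286 lower, with a median of -0.23, against 121 and 77 and a median of -0.02 with centred scaling and 72 and 1288 as the authors scaled the values. The 383 calls were 218 and 238 without lysogen replicates 1 and 2 of 10 min and 162 without non-lysogen replicate 2 of 10 min. At 20 min 280 were higher and 538 lower, 346 and 366 with centred scaling and 136 and 1531 as the authors scaled the values. The periplasmic chaperone gene skp was at 486.5 ± 99.2 RPKM in the lysogen and 2739 ± 103 in the non-lysogen at 20 min, and its responses differed by -2.06 ± 0.24 (adjusted p = 4.31e-05).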

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

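Of the tests of explanations in this part, that of DNA copies by 20 min had its prediction set down before its result was seen. All other tests of explanations were chosen only after the result was seen. The calls of genes and lists repeated here came from the comparisons described above.

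The count of host genes whose responses differed between the strains drew attention, with 6 at 5 min, 114 at 10 min and 430 at 20 min. Genes the rule named for such a difference were ybhD (adjusted p = 0.000373 at 5 min, 5.13e-05 at 10 min and 8.76e-05 at 20 min), ybhC (log2 difference 5.59, 4.91 and 4.08), cpxP (2.39), ybhA (1.77), ssb (0.92) and yjdK (adjusted p = 0.0445) at 5 min. At 10 min they were galK (4.61), galT (4.16), yncJ (3.89), uof (adjusted p = 0.000526), yagU (-3.60), ydhO (-3.15), flhD (-3.03) and ccmG (adjusted p = 0.0406). At 20 min they were galT (4.66), galK (4.36), hisL (adjusted p = 0.0009), dicC (adjusted p = 0.0314), gatB (adjusted p = 0.0287), ymgC (adjusted p = 0.00922) and yagU (-3.15). The lists with a call under an estimated correlation had median differences of 0.24 (gal side of attB, 5 min), 2.12 (Cpx, 10 min), 1.15 (gal side, 10 min), 1.99 (SOS, 20 min), -1.34 (leucine and isoleucine-valine, 20 min), 2.90 (gal side, 20 min) and 1.92 (bio side, 20 min). The calls of ybhA, ssb, yjdK, yncJ, ydhO, flhD, ccmG, dicC, gatB and ymgC ended without single libraries, as given with their values in the account above.

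From 2 min on, the share of reads outside the listed frames was higher in the lysogen than in any non-lysogen library (at most 0.0324%), with 0.113% at 2 min, 3.53% at 5 min, 5.25% at 10 min and 6.32% at 20 min. No explanation of this share was tested.

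The lambda reads of the non-lysogen were weighed as a first pattern. For the reads of 0 min, uninduced lysogen cells in these cultures are argued against. In the non-lysogen cI, rexA and rexB held 2.93% of the lambda reads at 0 min (9 of 307 reads, exact 95% interval 1.35 to 5.49). In the lysogen they held 60.7% (58.9 to 62.5). Reads shared with cryptic prophage genes are argued against as the whole source, as far as counterparts listed by gene name go. Of the reads, 86.8% (5135 of 5914, 85.9 to 87.7) lay in lambda genes without such a counterpart in the cryptic prophages. Sequences were not compared, so a counterpart of another name could be missed. Carry-over between libraries after harvest may account for the reads of 6 of the 10 non-lysogen libraries, those of 0, 2 and 5 min. Their lambda profiles were closest to a lysogen group of another time. The libraries of 10 and 20 min, with 827, 586, 1055 and 728 lambda reads, were closest to the lysogen of their own time. For these, lysogen cells induced in the same cultures cannot be told apart from carry-over. The intervals cover counting error only, and the libraries that gave the reads were not identified.

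The genes beside attB were weighed as a second pattern. More DNA copies of the region are argued against as the whole cause at 10 min, since the gal-side genes on the minus strand exceeded their plus-strand neighbours by 2.62 in the median. Transcription that runs on from the left operon of the prophage may account for that gap (one-sided exact permutation p = 0.00306, over 11440 splits of the 16 genes). By 20 min more DNA copies may add to it, as genes 20 to 100 kb away had median differences of 0.79 on the gal side and 1.25 on the bio side, against -0.18 for genes farther off. Neither RNA levels nor DNA levels were used here, so both remain hypotheses.

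The cryptic prophage genes were weighed as the third pattern. The 15 genes with a counterpart in lambda, listed by gene name, had a median difference of 1.59 at 20 min. NohD, the gene at that median, had 1 read in the lysogen at 0 min and 3 at 20 min. BorD had 73 reads in the lysogen at 0 min and the others at most 7, so the median lies near the floor. Lambda reads assigned to the genes with a counterpart, if they are of like sequence, may account for their higher median (one-sided permutation p = 0.00022, over the 17 genes without). The likeness of sequences was not examined. A general induction of the cryptic prophages by as much is argued against, since those 17 genes had a median of -0.07 (95% interval -1.86 to 0.45), with -0.15 for all host genes. Of them 15 had at most 18 reads in the lysogen at 0 min, so single values decide little. Their pooled reads, 97 to 156 in the lysogen and 60 to 186 in the non-lysogen, differed by 0.10 (95% interval -0.46 to 0.66, counting error only), against 3.77 (3.21 to 4.32) for the genes with a counterpart. Of the latter, tfaQ held 794 of 1177 reads in the lysogen at 20 min, and without it their difference was 2.27 (1.69 to 2.85). Genes within an operon are not independent, and a smaller induction is not excluded.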

How the results depend on the processing

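Voom, the lambda share of all features counted, the fits without both doubted 2 min libraries, and the check of scaling on list members were chosen only after the result was seen, while the other alternatives were planned. Of 529 called results for named genes, 370 kept their call in every setting except the stricter thresholds, and 0 changed direction in any setting run. The call was lost by 143 when any 1 library was left out, 70 with only the groups of a comparison in the fit, 41 with centring, 24 and 18 with the smaller and larger pseudocount, 21 with voom, 15 with the authors' scaling, 4 without the filter, 103 at an adjusted p under 0.01 and 110 with a change of at least 1. The stricter thresholds lower a count by construction, and a left-out library leaves a group with 1 sample, assumed to vary like the other groups. The authors' scaling counts lambda in the total, so it lowers host genes in the induced lysogen. For the other shifts the cause was not tested. Genes with few reads were limited by depth. The lambda share in the non-lysogen rests on 83 to 1457 reads per library and differed between replicates, with 0.158% and 0.0211% at 2 min, and the cause was not tested. A count-based test on read counts was planned and not run, since the values are RPKM. Leaving out lysogen replicate 2 and non-lysogen replicate 1 of 2 min gave 0 host calls for the 2 min interaction and for the strains at 2 min.

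At an adjusted p under 0.01 host calls were 349 (non-lysogen, 2 min), 352 (lysogen, 2 min), 3, 54 and 224 (interaction at 5, 10 and 20 min), and 0, 178 and 517 (lysogen against non-lysogen at 0, 10 and 20 min). With a change of at least 1 they were 362, 986 and 830 (non-lysogen, 2, 5 and 20 min), 332 and 907 (lysogen, 2 and 5 min), and 150 and 415 (lysogen against non-lysogen, 10 and 20 min). The pseudocount 10 times smaller gave 19 lambda calls at 2 min, 2 host calls in the 2 min interaction, and 6 and 1 between the strains at 0 and 2 min. The pseudocount 10 times larger and voom each gave 0 at 0 min. With only the groups of the contrast in the fit, 1 gene was called in the 2 min interaction and 0, 4, 187 and 528 between the strains at 0, 5, 10 and 20 min. Values as the authors scaled them gave 12, 579 and 1030 (interaction at 5, 10 and 20 min) and 173, 1360 and 1667 (between the strains). Median-of-ratios centring gave 198 between the strains at 10 min.

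The lambda share of values multiplied by length was 0.1314, 0.9484, 14.41 and 19.54% in the lysogen at 0, 2, 5 and 10 min and 0.09452% in the non-lysogen at 10 min. Of all features counted it was 0.1314, 0.9473, 13.9 and 18.51%, and 0.09449%. Without the 13 lambda frames above 0 in every non-lysogen library it was 0.6864, 10.71, 14.95 and 20.37% in the lysogen at 2, 5, 10 and 20 min and 0.0308, 0.06419 and 0.0671% in the non-lysogen at 5, 10 and 20 min.

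With an estimated inter-gene correlation the lists called were 1, 1, 7 and 4 in the non-lysogen (9, 14, 14 and 16 with the preset one), 1, 1, 9 and 9 in the lysogen (10, 13, 17 and 16), and 1, 2 and 4 in the interaction at 5, 10 and 20 min (8, 10 and 14).

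A replicate block gave 12 and 181 calls in the interaction at 5 and 10 min, 1 between the strains at 2 min and 1 list at 0 min, and changed no call of a named gene. Replicate numbers do not pair the samples by the labels, and the correlations of replicate differences between groups ran from -0.15 to 0.41 (median 0.13, 29 of 45 over 0.1). In the data, however, 20 of 20 libraries were closest to libraries of their own number. The 2 libraries of a group deviate from their mean by equal and opposite amounts. They must give the same outcome, so the count rests on 10 groups. It still points to something shared within a replicate number, which the main fit does not model.

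With each library left out, host calls ranged from 289 to 454, 1135 to 1245, 1277 to 1332 and 849 to 1072 (non-lysogen, 2 to 20 min), 342 to 447, 1035 to 1189, 1375 to 1489 and 1162 to 1426 (lysogen), 0 to 2, 3 to 17, 68 to 119 and 274 to 395 (interaction) and 1 to 12, 0 to 2, 11 to 25, 162 to 312 and 567 to 663 (between the strains, 0 to 20 min), and lambda calls from 17 to 21, 47 to 52, 68 to 68 and 70 to 72. The lambda share ranged from 0.1028 to 0.1233, 1.379 to 1.432, 19.81 to 20.94, 24.82 to 24.99 and 27.72 to 31.57% in the lysogen and 0.01084 to 0.03759, 0.0211 to 0.1585, 0.04282 to 0.06941, 0.1188 to 0.1331 and 0.08866 to 0.1394% in the non-lysogen.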

Other observations

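Some members of the lists were not named above. In the non-lysogen the ribosome hibernation factor gene rmf was at 21280 ± 1290 RPKM at 20 min against 8024 ± 353 at 0 min (SD, n = 2, log2 change 1.41 ± 0.11, adjusted p = 3.17e-07), and wrbA of the stationary phase list at 6735 ± 130 at 10 min against 2187 ± 146. The division gene ftsQ rose to 90.96 ± 4.84 RPKM at 10 min from 19.35 ± 12.4 (2.29 ± 0.38, adjusted p = 0.000161). Of the flagellar genes, flgB had 0 reads at 20 min, at least 5.27-fold fewer than at 0 min, and flgD 1 read against 24, a ratio of 25.3 (95% interval 4.12 to 1039). The responses of the strains at 20 min differed by -1.18 for the acid stress chaperone gene hdeB (adjusted p = 0.00577) and by -0.96 for the succinyl-CoA synthetase gene sucD (adjusted p = 0.00171).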
